A study of Homo sapiens with 12 samples.

How the data were processed

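RNA was sequenced from 22Rv1 cells, an established human prostate cancer line that is positive for the androgen receptor. The cells were kept for 24 h with the vehicle DMSO or with SNS032, LL-K9-3 or Thal-SNS032, each at 2 µM. Each of the 4 groups had 3 libraries, called biological triplicates in the labels. Per the labels' protocols, RNA was taken up in Trizol and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. The submitters' processing notes name the genome build hg19 and the tools STAR 2.5.3a and featureCounts 1.5.3. Per the file headers, the authors counted read pairs over the exons of each gene of an hg19 RefSeq annotation with featureCounts, and the recorded command set no strand option. Reads of a gene and of an overlapping gene on the other strand therefore cannot be told apart, and 6042 of the 27938 genes in the table overlap another gene. Of the 27938 genes, 375 lie on more than 1 sequence of the build. Values of such genes are uncertain, as are those of genes with near-identical copies.

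The values used were the authors' deposited whole-number counts per gene, which are not normalised. They were read from a table of all 12 libraries. The authors also deposited a file per library, and for 9 libraries it held counts identical to the table. For DMSO replicate 1, DMSO replicate 2 and Thal-SNS032 replicate 3 the file of the library held 1.96, 1.97 and 1.97 times the total in the table. Why these totals differ is not given in the sources used here. The table was used for every result, and the counts of the single files, as well as leaving these 3 libraries out, were alternatives chosen after seeing the data. Leaving them out keeps 1 DMSO and 2 Thal-SNS032 libraries. The spread was then pooled over the groups, and the lone DMSO library was assumed to vary like the others. The table holds 2 mitochondrial genes, RNR1 and RNR2, which are ribosomal RNAs, and no mitochondrial mRNA.

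Total counts per library ran from 10873816 to 16671761. Genes were kept by edgeR's filterByExpr with groups given and a minimum count of 10, which left 15763 genes. Libraries were scaled by the trimmed mean of M-values (TMM), and levels are given as edgeR's CPM of the scaled library. All 12 libraries entered 1 fit of group means with 8 residual degrees of freedom, and the 6 contrasts between groups were tested by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3). Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p of genes come from that test unless DESeq2's Wald test is named. Standard errors (SE) and 95% intervals of log2 fold changes come from the same fit. The common biological coefficient of variation was 10.1%. Except where stated, p-values of single genes measure the spread between these samples, and the labels do not say how the cultures were kept apart. Replicates were compared before they were averaged: the chi-square of their counts per degree of freedom lay between 2.19 and 20.1, above sampling noise for every pair within a group. It was 14.4 to 17.65 with DMSO, 5.41 to 20.1 with SNS032, 2.19 to 7.86 with LL-K9-3 and 2.46 to 4.17 with Thal-SNS032. DMSO pairs thus differed more in counts than LL-K9-3 or Thal-SNS032 pairs, and a spread pooled over the groups does not allow for this.

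In addition, 27 gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over all lists and comparisons, and again with the correlation estimated from the data. The lists cover P-TEFb and its regulators, other CDKs and cyclins, androgen receptor targets, MYC targets, immediate early genes, anti-apoptotic and pro-apoptotic genes, p53 targets, E2F and S phase genes, G2 and mitosis genes, DNA repair, histones, the integrated stress and unfolded protein response, heat shock, interferon and NF-kB targets. They also cover cholesterol synthesis, ribosomal proteins, mitochondrial mRNAs, nuclear oxidative phosphorylation subunits, luminal, basal, neuroendocrine, mesenchymal and leukocyte or endothelial markers, RNA polymerase III transcripts and zinc finger genes matched by their symbols. The list of mitochondrial mRNAs had 0 measured members and was not tested. At the preset correlation camera compares the members of a list with other genes as if nearly independent. Its p-values therefore do not measure the spread between cultures. With an estimated correlation 0 of the lists were called in any comparison, against 51 calls in 156 tests at the preset correlation. A test of each list against no change (fry) was run beside it; it does not compare a list with other genes.

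The lists, the comparisons, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The genes named in each comparison were CDK9, CCNT1, CCNT2, HEXIM1, AR, KLK3, MYC and MCL1. To these were added the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM over the 12 libraries and no overlap between the libraries of both groups. Between groups of 3, chance alone keeps the libraries apart in 10% of genes. From each list called by camera, members were taken from the 3 with the smallest adjusted p. Intervals on ratios of low counts are exact 95% intervals and cover counting error only.

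Alternatives were DESeq2's size factors, library size as the only scaling, no filter on low counts, DESeq2's Wald test (DESeq2 1.42.0), fits of the 2 groups compared alone, the replicate number as a block and leaving out each library in turn. A planned scaling on mitochondrial mRNAs was not run because the table holds none. The scaling matters in these data. TMM factors were 1.46 to 1.53 with DMSO, 1.11 to 1.20 with SNS032, 1.18 to 1.20 with LL-K9-3 and 0.486 to 0.497 with Thal-SNS032. With library size as the only scaling, log2 fold changes against DMSO shifted by -0.36 for SNS032, -0.33 for LL-K9-3 and -1.60 for Thal-SNS032. They shifted by 0.03 for LL-K9-3 against SNS032, by -1.24 for Thal-SNS032 against SNS032 and by 1.27 for LL-K9-3 against Thal-SNS032. All changes are given relative to the TMM scaling unless stated. The labels describe no spike-in, so a change in the total mRNA per cell was not measured.

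The steps were tested on simulated data before use. Counts were drawn from the real means of the DMSO libraries, and chosen genes were changed in the libraries standing for SNS032. With 14823 genes tested, edgeR recovered 67.7% of genes changed 1.5-fold, 85.2% of those changed 2-fold and 98.4% of those changed 4-fold. These shares are over the 65, 61 and 61 changed genes that passed the filter, of 67, 67 and 66 changed. Among 14609 unchanged genes edgeR made 5 false calls and DESeq2 made 9. Few genes were changed in these counts, whereas 66.9% to 80.9% of genes were called against DMSO in the real data. The simulation therefore did not test the scaling under so many changes. GC content was taken from the transcripts of GENCODE release 29 by gene symbol for 91.3% of the genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.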

Results

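Gene expression was measured by RNA sequencing in 22Rv1 prostate cancer cells kept for 24 h with DMSO, SNS032, LL-K9-3 or Thal-SNS032, in 3 libraries per group. The series is about small molecules that degrade the complex of CDK9 and cyclin T1, and the comparisons ask how each compound altered the mRNA of these cells and how the compounds differed. SNS032 is an inhibitor of cyclin-dependent kinases, among them CDK2, CDK7 and CDK9. Thal-SNS032 is SNS032 joined through a linker to thalidomide, which recruits a ubiquitin ligase. LL-K9-3 is known here by its code name and by the series' description of its compounds as degraders. CDK9 and a cyclin T form P-TEFb, the kinase that releases paused RNA polymerase II into elongation. All compounds were used at 2 µM for 24 h, so the comparisons among them are at matched dose and time.

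Total counts were 15768198 to 16671761 with DMSO, 15991903 to 16030508 with SNS032, 10873816 to 11821007 with LL-K9-3 and 14297873 to 14785424 with Thal-SNS032. Between 17403 and 17487 genes had a count with Thal-SNS032, and between 18294 and 19306 in the other groups. RNR2, the large ribosomal RNA of mitochondria, took 0.739% to 0.951% of the counts with DMSO and 2.35% to 2.64% with SNS032. It took 4.36% to 4.65% with LL-K9-3 and 6.90% to 7.12% with Thal-SNS032. The 10 most abundant genes took 4.61% to 5.24%, 6.23% to 6.82%, 8.10% to 8.62% and 14.1% to 14.4% in the same order of groups. Without the mitochondrial ribosomal RNAs these shares were 4.10% to 4.55%, 4.14% to 4.64%, 3.72% to 3.91% and 7.05% to 7.23%. On a principal component plot of log2 CPM the groups were separate, with the Thal-SNS032 libraries between 157 and 160 on a first component that held 59% of the variance and all others between -65.5 and -41.3.

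**Figure D1:**
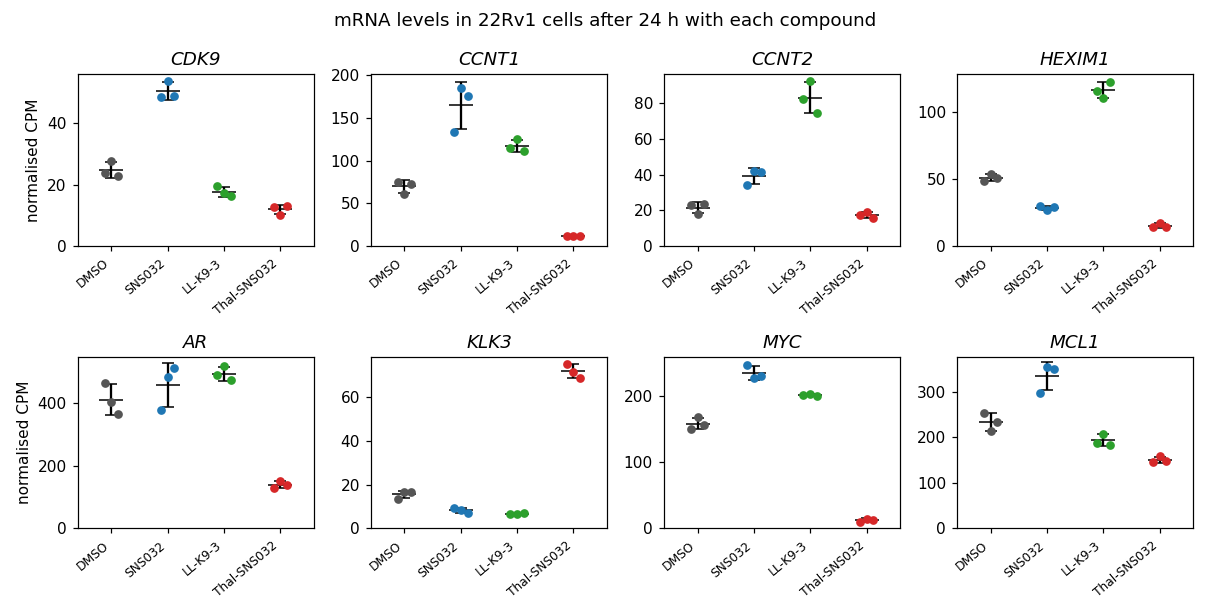
Normalised CPM (y axis, TMM scaling) of 8 genes fixed before the data were examined, by group (x axis), with points for the 3 libraries, a line at the mean and bars of 1 SD. MYC lay at 12.4 CPM with Thal-SNS032 and at 158 CPM with DMSO, while KLK3 lay at 71.5 and 15.5 CPM.

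With SNS032, mRNAs of P-TEFb itself rose. CDK9 (chromosome 9, 130548305 to 130553052) was at 50.5 ± 2.93 against 24.8 ± 2.5 CPM with DMSO (SD, n = 3 each), a 2.03-fold rise (log2 fold change 1.02 ± 0.11 SE, adjusted p = 3.15e-08). CCNT1 (chromosome 12, 49082241 to 49110781), which encodes cyclin T1, rose 2.36-fold (log2 1.24 ± 0.11, adjusted p = 9.19e-10). CCNT2 (chromosome 2, 135676392 to 135716915), which encodes cyclin T2, rose 1.84-fold (log2 0.88 ± 0.12, adjusted p = 1.10e-06). HEXIM1 (chromosome 17, 43224684 to 43229468), whose protein holds P-TEFb inactive, fell to 28.6 ± 1.67 against 51.2 ± 2.75 CPM (log2 -0.84 ± 0.10, adjusted p = 9.13e-08). MYC (chromosome 8, 128747680 to 128755197), a growth-promoting transcription factor, rose by 0.57 ± 0.10 on the log2 scale (adjusted p = 2.42e-05), and MCL1 (chromosome 1, 150547027 to 150552214), a survival factor of the BCL2 family, by 0.52 ± 0.09 (adjusted p = 3.26e-05). Exons of MCL1 overlap ADAMTSL4-AS1 in the annotation. AR (chromosome X, 66764465 to 66950461), the androgen receptor, was at 457 ± 70.6 against 410 ± 48.8 CPM and was not called (log2 0.15 ± 0.11, 95% interval -0.07 to 0.38, adjusted p = 0.209). KLK3 (chromosome 19, 51358171 to 51364020), the androgen receptor target that encodes prostate-specific antigen, fell to 8.34 ± 1.19 against 15.5 ± 1.64 CPM (log2 -0.90 ± 0.13, adjusted p = 1.50e-06). With library size as the only scaling AR turned to -0.20, and MYC and MCL1 were no longer called (log2 0.21, adjusted p = 0.0636 and log2 0.16, adjusted p = 0.156, edgeR). AR was called higher without SNS032 replicate 1 (log2 0.28, adjusted p = 0.0183) and with DESeq2's size factors (log2 0.25, adjusted p = 0.0414) or its Wald test (0.0432).

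MYC target, ribosomal protein, oxidative phosphorylation, heat shock, immediate early, p53, NF-kB and histone lists rose with SNS032. In the list of MYC targets of ribosome biogenesis 33 genes rose and 3 fell of 44 (camera adjusted p = 1.04e-07, and adjusted p = 0.234 with an estimated correlation), among them NOLC1 (log2 1.56 ± 0.08) and PES1 (log2 1.89 ± 0.10), factors of nucleolar ribosome assembly. Of the cytosolic ribosomal proteins 52 genes rose and 0 fell of 61 (adjusted p = 1.96e-08, and adjusted p = 0.531 with an estimated correlation), with RPLP2 at 1501 ± 248 against 583 ± 107 CPM. Of the nuclear subunits of oxidative phosphorylation 37 genes rose and 1 fell of 40 (adjusted p = 4.79e-10, and adjusted p = 0.425 with an estimated correlation), with the complex III subunit UQCRFS1 up by 2.24 ± 0.10. RNR2 rose beside these lists (log2 1.91 ± 0.12 SE). In the heat shock list 14 genes rose and 1 fell of 20 (adjusted p = 1.43e-05, and adjusted p = 0.248 with an estimated correlation). Its members BAG3, a co-chaperone, and HSPA1B, an inducible HSP70 whose near-identical copy HSPA1A makes the counts uncertain, rose by 2.48 ± 0.10 and 2.14 ± 0.11. Of the immediate early genes 22 genes rose and 6 fell of 34 (adjusted p = 0.00231, and adjusted p = 0.402 with an estimated correlation), led by the nuclear receptor NR4A1 (log2 2.44 ± 0.10) and the AP-1 member JUNB (log2 1.46 ± 0.10). Of the p53 targets 17 genes rose and 4 fell of 30 (adjusted p = 0.00367, and adjusted p = 0.216 with an estimated correlation), with the CDK inhibitor CDKN1A (p21) at 312 ± 26.5 against 90.2 ± 8.46 CPM and the zinc finger gene ZMAT3 up by 2.00 ± 0.15. Of the NF-kB targets 11 genes rose and 1 fell of 14 (adjusted p = 0.0194, and adjusted p = 0.363 with an estimated correlation), including TNFAIP2 (log2 1.26 ± 0.14) and BCL3 (log2 1.24 ± 0.14). Of the replication-dependent histones 25 genes rose and 1 fell of 38 (adjusted p = 0.000198, and adjusted p = 0.248 with an estimated correlation). HIST2H2BE and HIST1H2BK rose by 2.55 ± 0.11 and 2.59 ± 0.13, and reads of such similar genes are uncertain. Levels in the histone list were low, with a median of 1.77 CPM over the 12 libraries. Scaled by library size alone, 27 MYC targets were higher and 10 lower, 31 and 7 ribosomal proteins (median log2 fold change 0.24 against 0.60 with TMM), 15 and 10 p53 targets and 18 and 9 immediate early genes.

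The lists that fell with SNS032 were those of DNA repair, S phase, mitosis and the stress response. Of the DNA repair genes 2 genes rose and 36 fell of 42 (camera adjusted p = 1.04e-07, and adjusted p = 0.246 with an estimated correlation). BRCA1 and BRCA2, both needed for homologous recombination, fell to 13.8 ± 2.38 against 92.4 ± 13.5 CPM and to 3.04 ± 0.166 against 29.9 ± 5.56 CPM. Of the E2F and S phase genes 6 genes rose and 34 fell of 44 (adjusted p = 3.18e-07, and adjusted p = 0.138 with an estimated correlation), with RRM2, a subunit of ribonucleotide reductase, at -2.57 ± 0.12 on the log2 scale and the DNA primase subunit PRIM1 at -2.28 ± 0.14. Of the G2 and mitosis genes 6 genes rose and 23 fell of 40 (adjusted p = 0.000814, and adjusted p = 0.248 with an estimated correlation), with the topoisomerase gene TOP2A at -2.01 ± 0.11 and the spindle gene ASPM at -2.03 ± 0.12. In the list of the integrated stress and unfolded protein response 5 genes rose and 19 fell of 30 (adjusted p = 0.00845, and adjusted p = 0.216 with an estimated correlation). Members went both ways: DDIT3, which encodes the stress factor CHOP, fell (log2 -3.68 ± 0.13), while the asparagine synthetase gene ASNS rose by 1.93 ± 0.12. Adjusted over the list alone, the counts were the same except for the MYC targets (33 higher, 4 lower), the mitosis genes (6 higher, 24 lower) and the ribosomal proteins (52 higher, 1 lower). By library size alone 1 gene was higher and 38 lower in the E2F list, 1 and 31 in the mitosis list and 2 and 24 in the stress response list.

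The remaining lists were not called by camera, at adjusted p from 0.105 to 0.875. They were P-TEFb and its regulators (11 higher and 7 lower of 22), other CDKs and cyclins (9 higher and 7 lower of 24), androgen receptor targets (10 higher and 16 lower of 36), anti-apoptotic genes (7 higher and 5 lower of 14) and pro-apoptotic genes (6 higher and 6 lower of 20). Likewise not called were interferon-stimulated genes (4 higher and 15 lower of 24), cholesterol synthesis (4 higher and 12 lower of 24), luminal (8 higher and 3 lower of 15), basal (4 higher and 2 lower of 7) and neuroendocrine markers (1 higher and 5 lower of 10). The same held for mesenchymal markers (2 higher and 5 lower of 13), leukocyte and endothelial markers (2 higher and 0 lower of 4), RNA polymerase III transcripts (2 higher and 0 lower of 3) and zinc finger genes (103 higher and 184 lower of 479). The zinc finger list was matched by symbol and also holds ZNF genes without a KRAB domain. Adjusted over the list alone the counts differed for other CDKs and cyclins (10 higher, 8 lower), androgen receptor targets (11 and 16), interferon-stimulated genes (5 and 15) and zinc finger genes (102 and 179). The mesenchymal list had a median log2 fold change of -0.28 and a mean of 0.03. Cholesterol synthesis was called lower with library size as the only scaling (adjusted p = 0.0202). P-TEFb and its regulators, other CDKs and cyclins and anti-apoptotic genes had medians of 0.28, 0.11 and 0.33 with TMM and of -0.08, -0.25 and -0.03 by library size.

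The genes that rose most with SNS032 were LRRN4, CSAG4, MIR663A, MIR663AHG, HMOX1 and SLC25A18. HMOX1 (chromosome 22, 35777060 to 35790207), the heme oxygenase induced by oxidative stress, rose from 2.46 to 63.6 CPM (log2 4.69 ± 0.19, adjusted p = 3.73e-15). SLC25A18, a mitochondrial glutamate carrier that overlaps LOC101929372, rose by 4.44 ± 0.20. LRRN4 (chromosome 20, 6021192 to 6034726) had 359 counts with SNS032 and 2 with DMSO, a 233-fold ratio (95% counting interval 64.0 to 1930), and its log2 fold change of 7.50 ± 0.44 became 9.59 without DMSO replicate 1. CSAG4, whose exons overlap MAGEA12, was at 25.4 ± 0.829 against 0.167 ± 0.114 CPM (log2 7.19 ± 0.23, and 7.84 without DMSO replicate 2). MIR663AHG (chromosome 20, 26167655 to 26189869), a long non-coding RNA, was at 45.4 ± 8.23 against 0.957 ± 0.209 CPM and rose by 5.56 ± 0.16, or by 6.22 with the counts of the single files. MIR663A, which lies within it, rose by 6.32 ± 0.27. Whether MIR663A and MIR663AHG collect reads of ribosomal RNA stays open, here and with the other compounds. DDIT3 (chromosome 12, 57910371 to 57914300, overlapping MARS) fell most, to 15.7 ± 3.10 against 201 ± 2.88 CPM (log2 -3.68 ± 0.13, adjusted p = 3.80e-16). SLITRK6 (chromosome 13, 86366922 to 86373483), a neuronal membrane protein, fell (log2 -3.47 ± 0.13), as did BRCA2 (-3.30 ± 0.17), CFAP44 (-3.17 ± 0.23), the glutathione-degrading enzyme gene CHAC1 (-3.15 ± 0.20) and GTPBP2 (-3.13 ± 0.14). CFAP44 overlaps BOC and CFAP44-AS1, and GTPBP2 overlaps POLH. In all, 5039 genes were higher and 5505 lower of 15763 tested, 1796 and 2612 of them by at least 2-fold. With library size as the only scaling 3124 were higher, and the share of higher genes among those called was 28.1% against 47.8% with TMM.

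With LL-K9-3, CDK9 fell while both cyclin T genes rose. CDK9 was at 17.7 ± 1.67 against 24.8 ± 2.5 CPM with DMSO (SD, n = 3 each; log2 -0.49 ± 0.12 SE, adjusted p = 0.000888). CCNT1 rose to 117 ± 7.02 against 69.8 ± 7.62 CPM (log2 0.75 ± 0.11, adjusted p = 2.01e-06), and CCNT2 rose 3.89-fold (log2 1.96 ± 0.12, adjusted p = 1.54e-12). HEXIM1 rose to 117 ± 6.23 against 51.2 ± 2.75 CPM (log2 1.19 ± 0.10, adjusted p = 1.43e-10). KLK3 fell to 6.81 ± 0.401 against 15.5 ± 1.64 CPM (log2 -1.19 ± 0.14, adjusted p = 3.99e-08). MYC was higher by 0.34 ± 0.10 (adjusted p = 0.00358), but stood at log2 0.01 (adjusted p = 0.897, edgeR) with library size as the only scaling. MCL1 was lower at log2 -0.27 ± 0.09 (adjusted p = 0.0120). Its call was lost with DESeq2's size factors (adjusted p = 0.0998) or its Wald test (0.0764) and without DMSO replicate 1 (0.0502), LL-K9-3 replicate 1 (0.0517) or LL-K9-3 replicate 3 (0.0519). AR was higher by 0.26 ± 0.11 (adjusted p = 0.0311). The call of AR was lost without DMSO replicate 2 (0.0828), DMSO replicate 3 (0.158), LL-K9-3 replicate 1 (0.0606) or LL-K9-3 replicate 2 (0.0942) and without the filter on low counts (0.0835), and it turned to -0.07 with library size as the only scaling.

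Immediate early genes, histones, heat shock genes and oxidative phosphorylation genes rose as lists with LL-K9-3. Of the immediate early genes 23 genes rose and 7 fell of 34 (camera adjusted p = 0.000985, and adjusted p = 0.400 with an estimated correlation). FOS, the AP-1 subunit, rose from 5.75 ± 0.526 to 99.6 ± 8.62 CPM, JUNB by 3.26 ± 0.11 on the log2 scale and IER2 by 3.08 ± 0.10. Of the replication-dependent histones, a list with a low median of 1.77 CPM over the 12 libraries, 30 genes rose and 1 fell of 38 (adjusted p = 0.000266, and adjusted p = 0.248 with an estimated correlation). Among them HIST2H2BE rose by 2.09 ± 0.11 and HIST1H2BK by 1.13 ± 0.13. In the heat shock list 12 genes rose and 3 fell of 20 (adjusted p = 0.0355, and adjusted p = 0.473 with an estimated correlation), with BAG3 up by 1.99 ± 0.10 and the chaperone gene HSP90AB1 by 1.45 ± 0.09. This call was lost with library size as the only scaling (adjusted p = 0.0729) and without DMSO replicate 1 (0.0541) or DMSO replicate 2 (0.0518). Of the oxidative phosphorylation subunits 27 genes rose and 2 fell of 40 (adjusted p = 0.000666, and adjusted p = 0.589 with an estimated correlation), with NDUFA10 of complex I up by 0.76 ± 0.09 and SDHA of complex II by 0.74 ± 0.08. RNR2 rose beside them (log2 2.73 ± 0.12 SE). Scaled by library size alone, 19 oxidative phosphorylation genes were higher and 9 lower, 17 and 9 immediate early genes and 8 and 6 heat shock genes.

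Cell cycle, DNA repair, stress response, pro-apoptotic and zinc finger lists fell with LL-K9-3. Of the E2F and S phase genes 8 genes rose and 26 fell of 44 (camera adjusted p = 0.00201, and adjusted p = 0.217 with an estimated correlation), with PRIM1 at -2.63 ± 0.15 and the replication licensing gene CDC6 at -2.02 ± 0.12 on the log2 scale. Of the G2 and mitosis genes 7 genes rose and 21 fell of 40 (adjusted p = 0.0224, and adjusted p = 0.400 with an estimated correlation), with cyclin B1 (CCNB1) at 24.7 ± 1.79 against 125 ± 15 CPM and the kinase gene AURKB at -2.61 ± 0.15 on the log2 scale. Of the DNA repair genes 10 genes rose and 28 fell of 42 (adjusted p = 0.0141, and adjusted p = 0.456 with an estimated correlation), with BRCA1 at -2.64 ± 0.14 and FANCF at -2.33 ± 0.13. In the integrated stress and unfolded protein response 6 genes rose and 19 fell of 30 (adjusted p = 0.0101, and adjusted p = 0.216 with an estimated correlation), including XBP1, the transcription factor of the unfolded protein response, at 39.5 ± 2.44 against 176 ± 14.3 CPM and TRIB3 at -2.07 ± 0.11 on the log2 scale. Of the pro-apoptotic genes 3 genes rose and 15 fell of 20 (adjusted p = 0.0407, and adjusted p = 0.271 with an estimated correlation), with PMAIP1 (NOXA) at -1.54 ± 0.15 and DIABLO, which overlaps B3GNT4 and LOC101593348, at -1.30 ± 0.12. Of the zinc finger genes 93 genes rose and 284 fell of 479 (adjusted p = 0.000456, and adjusted p = 0.402 with an estimated correlation), with ZNF672 at -2.34 ± 0.12 and ZNF43 at -2.49 ± 0.13. Counts adjusted over the list alone were the same in the called lists except for zinc finger genes (93 higher, 285 lower). By library size alone 4 genes were higher and 32 lower in the E2F list and 4 and 30 in the mitosis list.

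Lists not called with LL-K9-3, at camera adjusted p from 0.0836 to 0.924, were P-TEFb and its regulators (12 higher and 8 lower of 22), other CDKs and cyclins (9 higher and 11 lower of 24), androgen receptor targets (9 higher and 19 lower of 36) and MYC targets (17 higher and 19 lower of 44). Neither anti-apoptotic genes (4 higher and 8 lower of 14), p53 targets (10 higher and 12 lower of 30), interferon-stimulated genes (5 higher and 14 lower of 24), NF-kB targets (5 higher and 5 lower of 14) nor cholesterol synthesis (8 higher and 12 lower of 24) were called. Ribosomal proteins (19 higher and 7 lower of 61), luminal (6 higher and 7 lower of 15), basal (3 higher and 1 lower of 7) and neuroendocrine markers (4 higher and 3 lower of 10) and RNA polymerase III transcripts (2 higher and 0 lower of 3) were not called either. Mesenchymal markers (8 higher and 2 lower of 13) included COL1A1, a collagen gene chosen after its values were seen, at 94.1 against 8.04 CPM. Of the leukocyte and endothelial markers (3 higher and 0 lower of 4), CD14, CD68 and CSF1R were at 4.71, 12.4 and 1.41 CPM against 0.138, 2.63 and 0.0667 with DMSO, also named after their values were seen. That list was called higher without LL-K9-3 replicate 1 (adjusted p = 0.0465) and with library size as the only scaling (adjusted p = 0.0301), and androgen receptor targets were called without the filter on low counts (adjusted p = 0.0159). RNA polymerase III transcripts lost both calls when adjusted over the list alone, and the other uncalled lists kept their counts. Median and mean log2 fold change had opposite signs for other CDKs and cyclins (0.10 and -0.02), p53 targets (-0.12 and 0.06) and luminal markers (0.07 and -0.26). For neuroendocrine markers both lay below 0 (-0.001 and -0.08) while camera's direction was upward. The ribosomal protein median was 0.13 with TMM and -0.20 with library size as the only scaling. That scaling, a shift of -0.33, also took other medians below 0. They were those of P-TEFb and its regulators (0.30 with TMM), other CDKs and cyclins (0.10), MYC targets (0.02) and luminal markers (0.07).

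The largest rises with LL-K9-3 were of MIR663A, LRRN4, MIR663AHG, CSAG4, RPS14P3 and PANO1. MIR663AHG rose from 0.957 to 221 CPM (log2 7.84 ± 0.16, adjusted p = 1.11e-20), or by 8.50 with the counts of the single files, and MIR663A by 8.51 ± 0.24. LRRN4 had 493 counts against 2 with DMSO, a 438-fold ratio (95% counting interval 120 to 3620), and its log2 fold change went from 8.41 to 10.5 without DMSO replicate 1. CSAG4 rose by 7.55 ± 0.23, or by 8.19 without DMSO replicate 2. RPS14P3 (chromosome 1, 19934301 to 19935138), a pseudogene of a ribosomal protein gene whose reads are uncertain, rose by 6.43 ± 0.23, and PANO1, which overlaps PIDD1 and SLC25A22, by 5.93 ± 0.26. GTPBP2 (chromosome 6, 43588218 to 43596983) fell most (log2 -4.61 ± 0.16, adjusted p = 7.02e-17), followed by RAB36 (-3.99 ± 0.19), DDIT3 (-3.87 ± 0.13), the connexin gene GJD3 (-3.74 ± 0.22), PRR15L (-3.71 ± 0.25) and SLITRK6 (-3.70 ± 0.13). In all, 5613 genes were higher and 5876 lower, 2693 and 3103 of them by at least 2-fold. Higher genes made up 48.9% of those called, and 33.4% with library size as the only scaling.

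With Thal-SNS032, mRNAs of P-TEFb, MYC, MCL1 and AR fell. CDK9 was at 11.9 ± 1.60 against 24.8 ± 2.5 CPM with DMSO (SD, n = 3 each; log2 -1.06 ± 0.13 SE, adjusted p = 1.09e-07). CCNT1 was 5.97-fold lower (log2 -2.58 ± 0.14, adjusted p = 1.22e-14), and HEXIM1 3.38-fold lower (log2 -1.76 ± 0.11, adjusted p = 5.77e-13). MYC fell to 12.4 ± 2.98 against 158 ± 8.96 CPM (log2 -3.67 ± 0.13, adjusted p = 3.75e-18), and MCL1 to 151 ± 6.94 against 233 ± 19.6 CPM (log2 -0.63 ± 0.10, adjusted p = 1.75e-06). AR fell to 139 ± 11.3 against 410 ± 48.8 CPM (log2 -1.56 ± 0.11, adjusted p = 4.12e-12). KLK3 rose to 71.5 ± 3.15 against 15.5 ± 1.64 CPM, 4.61-fold (log2 2.20 ± 0.12, adjusted p = 2.24e-14). CCNT2 was at 17.2 ± 1.67 against 21.4 ± 3.15 CPM with overlapping libraries (log2 -0.31 ± 0.14, adjusted p = 0.0444). This call was lost with DESeq2's size factors (log2 -0.17, adjusted p = 0.251) or its Wald test (0.251), in a fit of these groups alone (0.0793) and without DMSO replicate 1 (0.116), DMSO replicate 3 (0.127), Thal-SNS032 replicate 1 (0.0725) or Thal-SNS032 replicate 3 (0.154). Over the alternatives other than leaving out 1 library, log2 fold changes ran from -1.91 to -0.17 for CCNT2 and from -2.23 to -0.49 for MCL1. KLK3 ran from 0.61 to 2.34 and stood at 0.61 with library size as the only scaling.

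Ribosomal protein and oxidative phosphorylation mRNAs rose nearly as a whole with Thal-SNS032. Of the ribosomal proteins 60 genes rose and 1 fell of 61 (camera adjusted p = 3.45e-19, and adjusted p = 0.408 with an estimated correlation), with a median log2 fold change of 2.62 that was 1.03 with library size as the only scaling. RPL22 rose from 307 ± 33.9 to 4094 ± 122 CPM, and RPS12 by 3.85 ± 0.13 on the log2 scale. Of the oxidative phosphorylation subunits 40 genes rose and 0 fell of 40 (adjusted p = 4.23e-16, and adjusted p = 0.357 with an estimated correlation), with a median of 2.81, or 1.21 by library size. ATP5B, a catalytic subunit of ATP synthase, rose from 1543 ± 81.5 to 17280 ± 357 CPM, and UQCRC2 of complex III by 3.43 ± 0.10. RNR2 rose beside these lists (log2 4.64 ± 0.13 SE). Of the replication-dependent histones 30 genes rose and 1 fell of 38 (adjusted p = 0.000266, and adjusted p = 0.249 with an estimated correlation), with HIST1H2BD up by 3.76 ± 0.18 and the linker histone gene HIST1H1E by 4.02 ± 0.24. By library size alone 16 histone genes were higher and 8 lower, with a median of 0.59 against 2.18, and 35 and 4 oxidative phosphorylation genes. The histone genes were low, with a median of 1.77 CPM over the 12 libraries. In cholesterol synthesis 16 genes rose and 3 fell of 24 (adjusted p = 0.0119, and adjusted p = 0.325 with an estimated correlation). Among its enzymes MSMO1 rose by 2.85 ± 0.12 and DHCR7 by 2.05 ± 0.08, while SQLE, the squalene epoxidase, fell (log2 -3.48 ± 0.14). The cholesterol call was lost with library size as the only scaling (adjusted p = 0.711), where the median went from 1.11 to -0.49.

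Mitosis, DNA repair, stress response and zinc finger lists fell with Thal-SNS032. Of the G2 and mitosis genes 5 genes rose and 35 fell of 40 (camera adjusted p = 8.23e-07, and adjusted p = 0.216 with an estimated correlation). ASPM was at 3.95 ± 0.781 against 127 ± 18.4 CPM, and MKI67, the proliferation marker, at 19.3 ± 2.11 against 228 ± 34.3 CPM. Of the DNA repair genes 8 genes rose and 28 fell of 42 (adjusted p = 0.0203, and adjusted p = 0.473 with an estimated correlation), with BRCA1 at -2.66 ± 0.14 on the log2 scale and BRCA2 at -3.62 ± 0.20. In the integrated stress and unfolded protein response 7 genes rose and 21 fell of 30 (adjusted p = 0.0142, and adjusted p = 0.216 with an estimated correlation), with DDIT3 at 5.86 ± 1.01 against 201 ± 2.88 CPM and DDIT4, an inhibitor of mTORC1 signalling, at -4.71 ± 0.14 on the log2 scale. Of the zinc finger genes 26 genes rose and 404 fell of 479 (adjusted p = 1.30e-11, and adjusted p = 0.234 with an estimated correlation), with ZNF672 at -3.67 ± 0.15 and ZNF740, which overlaps CSAD, at -3.52 ± 0.14. Zinc finger genes counted 26 higher and 405 lower when adjusted over the list alone, and the other called lists kept their counts. By library size alone edgeR called 41 DNA repair genes lower and none higher, and 27 stress response genes lower and 1 higher.

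Lists not called with Thal-SNS032, at camera adjusted p from 0.0670 to 0.888, included P-TEFb and its regulators (8 higher and 14 lower of 22), other CDKs and cyclins (12 higher and 11 lower of 24), androgen receptor targets (17 higher and 15 lower of 36) and MYC targets (14 higher and 27 lower of 44). Immediate early genes (15 higher and 13 lower of 34), anti-apoptotic (3 higher and 10 lower of 14) and pro-apoptotic genes (5 higher and 14 lower of 20), p53 targets (6 higher and 22 lower of 30) and E2F and S phase genes (16 higher and 25 lower of 44) were not called. Nor were heat shock genes (8 higher and 10 lower of 20), interferon-stimulated genes (11 higher and 6 lower of 24), NF-kB targets (1 higher and 6 lower of 14), luminal (6 higher and 9 lower of 15), basal (5 higher and 2 lower of 7) and neuroendocrine markers (5 higher and 3 lower of 10). Mesenchymal markers (7 higher and 2 lower of 13), leukocyte and endothelial markers (2 higher and 0 lower of 4) and RNA polymerase III transcripts (3 higher and 0 lower of 3) completed the set. Adjusted over the list alone, counts of these differed only for E2F and S phase genes (16 higher, 26 lower). Median and mean differed in sign for other CDKs and cyclins (0.27 and -0.31), and androgen receptor targets had a median of -0.08 under an upward camera direction. With library size as the only scaling the medians of other CDKs and cyclins, immediate early genes, interferon-stimulated genes, basal, neuroendocrine and mesenchymal markers turned from above to below 0. In the same scaling camera called P-TEFb and its regulators (adjusted p = 0.0442), MYC targets (0.00301), p53 targets (0.0474) and RNA polymerase III transcripts (0.0153). Without the filter on low counts it called pro-apoptotic genes (0.0402), MYC targets (0.0091) and p53 targets (0.00468). By library size alone 4 androgen receptor targets were higher and 27 lower (median -1.68), 1 and 39 MYC targets, 1 and 27 p53 targets, 5 and 36 E2F genes and 1 and 15 heat shock genes.

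The largest rises with Thal-SNS032 were of MIR663A, MIR663AHG, MIR7641-2, CSAG4, ARC and KLKP1. MIR663AHG rose from 0.957 ± 0.209 to 731 ± 32.6 CPM (log2 9.57 ± 0.17, adjusted p = 2.16e-22), and MIR663A by 10.28 ± 0.24. KLKP1 (chromosome 19, 51385352 to 51399654), a pseudogene between KLK2 and KLK4, rose from 5.95 ± 0.872 to 724 ± 12.7 CPM (log2 6.92 ± 0.14, adjusted p = 2.18e-21). ARC (chromosome 8, 143692405 to 143695833), an activity-regulated neuronal gene, rose by 7.64 ± 0.18. CSAG4 rose by 8.02 ± 0.22, or by 8.65 without DMSO replicate 2. MIR7641-2, which is annotated on several sequences and overlaps SIAE, rose by 8.27 ± 0.35, or by 9.92 without DMSO replicate 2. Its rise ran from 6.71 to 11.7 over the alternatives other than leaving out 1 library. Among the falls, MAGEE1 (chromosome X, 75648046 to 75651746) had 1 count with Thal-SNS032 and 416 with DMSO, a 124-fold ratio (95% counting interval 22.1 to 4910), and its log2 fold change went from -6.73 to -9.58 without Thal-SNS032 replicate 2. SLITRK6 fell as well (log2 -6.20 ± 0.18), as did CHAC1 (-5.99 ± 0.33), the transcription factor gene ZSCAN9 (-5.83 ± 0.37), the vasopressin receptor gene AVPR1A (-5.27 ± 0.32) and the kinase gene STK17B (-5.49 ± 0.35), which was at -6.69 without Thal-SNS032 replicate 3. In all, 5728 genes were higher and 7019 lower, 4235 and 5359 of them by at least 2-fold. Scaled by library size alone, 2113 were higher and 11714 lower. Higher genes were then 15.3% of those called against 44.9%, and 2059 of the genes called higher with TMM were called lower.

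**Figure D2:**
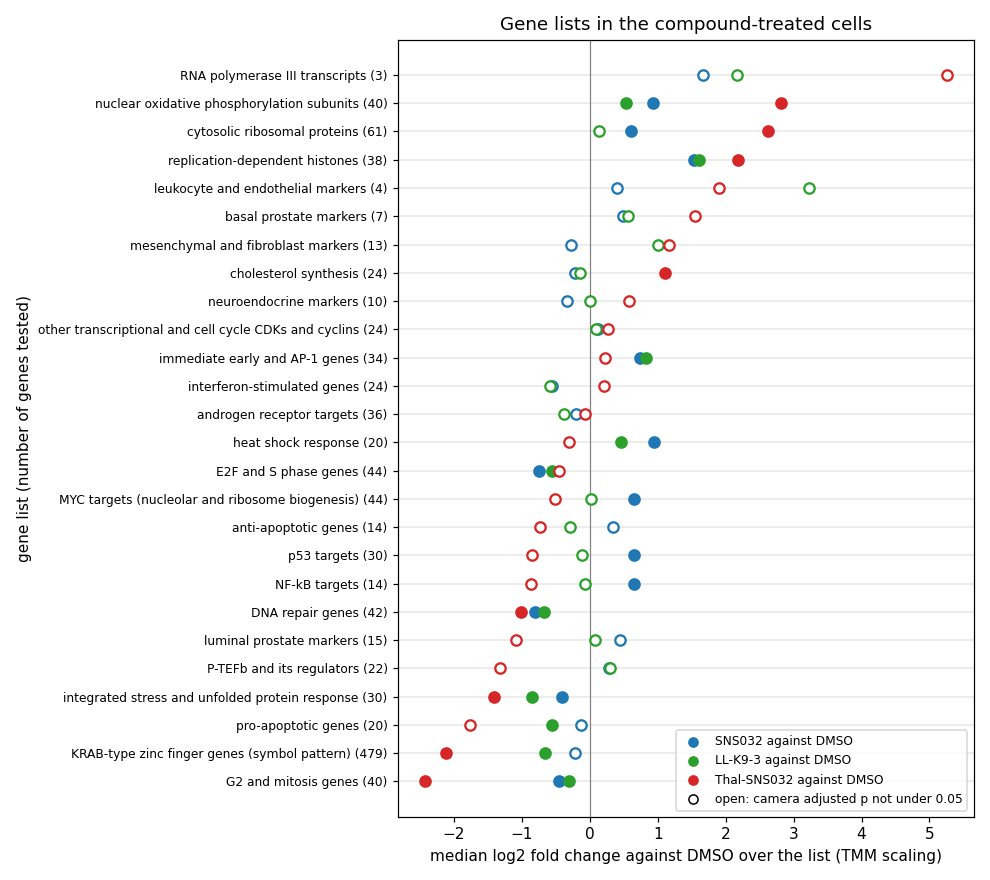
Median log2 fold change against DMSO (x axis, TMM scaling) over the members of each gene list (y axis, number of genes tested in brackets) for the 3 compounds, filled where camera called the list at its preset correlation. The ribosomal protein median was 2.62 with Thal-SNS032, 0.60 with SNS032 and 0.13 with LL-K9-3, and the last was -0.20 with library size as the only scaling; the median of cholesterol synthesis with Thal-SNS032 likewise went from 1.11 to -0.49.

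Thal-SNS032 and SNS032, which differ by the joined thalidomide, were compared directly. CDK9 and both cyclin T genes were lower with Thal-SNS032. The differences were, for CDK9, -2.08 ± 0.13 (95% interval -2.36 to -1.81, adjusted p = 3.66e-13), for CCNT1 -3.82 ± 0.14 (-4.11 to -3.53, adjusted p = 1.28e-17) and for CCNT2 -1.19 ± 0.14 (-1.47 to -0.90, adjusted p = 2.26e-08) on the log2 scale. HEXIM1 differed by -0.91 ± 0.12 (-1.16 to -0.67), AR by -1.71 ± 0.11 (-1.95 to -1.48) and MCL1 by -1.15 ± 0.10 (-1.35 to -0.95), at adjusted p of 1.25e-07, 6.89e-13 and 6.44e-11. MYC was at 12.4 ± 2.98 against 235 ± 11.1 CPM (log2 -4.24 ± 0.13, 95% interval -4.50 to -3.98, adjusted p = 1.01e-18). KLK3 went the other way, at 71.5 ± 3.15 against 8.34 ± 1.19 CPM (log2 3.10 ± 0.13, 95% interval 2.83 to 3.37, adjusted p = 1.44e-16).

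Of P-TEFb and its regulators 4 genes rose and 15 fell of 22 with Thal-SNS032 (camera adjusted p = 0.0164, and adjusted p = 0.246 with an estimated correlation), with the elongation factor gene MLLT1 at -2.39 ± 0.12 and, in the opposite direction, the NELF subunit gene NELFCD at 1.55 ± 0.09. Of the MYC targets 5 genes rose and 35 fell of 44 (adjusted p = 3.15e-06, and adjusted p = 0.246 with an estimated correlation), with LDHA, the lactate dehydrogenase, at -3.09 ± 0.10 and POLR1A, the large subunit of RNA polymerase I, at -3.75 ± 0.13. Of the p53 targets 5 genes rose and 24 fell of 30 (adjusted p = 0.000673, and adjusted p = 0.186 with an estimated correlation), with SESN2 at -4.30 ± 0.18. Of the G2 and mitosis genes 6 genes rose and 33 fell of 40 (adjusted p = 0.000155, and adjusted p = 0.246 with an estimated correlation), with the kinase gene AURKA at -3.84 ± 0.14. In the heat shock list 5 genes rose and 12 fell of 20 (adjusted p = 0.0478, and adjusted p = 0.473 with an estimated correlation), with HSPA8 at -4.83 ± 0.14, a call lost without DMSO replicate 2 (0.0518) or SNS032 replicate 1 (0.0638). Of the zinc finger genes 24 genes rose and 389 fell of 479 (adjusted p = 7.30e-11, and adjusted p = 0.234 with an estimated correlation), with ZNF263 at -4.27 ± 0.14. Higher with Thal-SNS032 were ribosomal proteins, where 59 genes rose and 1 fell of 61 (adjusted p = 7.53e-16, and adjusted p = 0.429 with an estimated correlation), and RPSA was at 23800 ± 682 against 3187 ± 513 CPM. Of the oxidative phosphorylation subunits 38 genes rose and 2 fell of 40 (adjusted p = 3.10e-11, and adjusted p = 0.402 with an estimated correlation), with NDUFS1 up by 3.07 ± 0.10, and RNR2 was higher beside them (log2 2.73 ± 0.12 SE). In cholesterol synthesis 19 genes rose and 5 fell of 24 (adjusted p = 0.00161, and adjusted p = 0.248 with an estimated correlation), with the low-density lipoprotein receptor gene LDLR up by 2.01 ± 0.09 and SQLE at -3.50 ± 0.14. The cholesterol median was 1.26 with TMM and 0.02 with library size as the only scaling, where 10 of its genes were higher and 9 lower. In that scaling 2 P-TEFb regulators were higher and 20 lower, 2 and 16 heat shock genes, 47 and 8 ribosomal proteins and 28 and 7 oxidative phosphorylation genes.

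Adjusted over the list alone, counts of the called lists were the same except for mitosis genes (6 higher, 34 lower) and zinc finger genes (24 higher, 391 lower). Lists not called included androgen receptor targets (17 higher and 15 lower of 36, adjusted p = 0.714), E2F and S phase genes (22 higher and 16 lower of 44, or 23 and 16 adjusted over the list alone, adjusted p = 0.181) and DNA repair genes (19 higher and 17 lower of 42, adjusted p = 0.738). The median of the DNA repair list was 0.19 and its mean -0.07. The integrated stress list (8 higher and 19 lower of 30, adjusted p = 0.0836) was not called either. It was called lower with library size as the only scaling (0.00878) and without the filter on low counts (0.00672).

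The largest rises from SNS032 to Thal-SNS032 were of MIR7641-2, HCG15, SOCS1, EML2-AS1, KLKP1 and RN7SL832P. MIR7641-2 had 605 counts against 2, a 782-fold ratio (95% counting interval 216 to 6470). HCG15 (chromosome 6, 28952526 to 28956344), a long non-coding RNA, was at 222 ± 6.62 against 0.985 ± 0.184 CPM (log2 7.80 ± 0.15, adjusted p = 1.21e-21), and SOCS1 (chromosome 16, 11348274 to 11350039), a suppressor of cytokine signalling, rose by 6.85 ± 0.27. EML2-AS1, which is antisense to EML2 and cannot be told apart from it without strand, rose by 6.56 ± 0.15, KLKP1 by 6.55 ± 0.14 and RN7SL832P, a pseudogene of an abundant small RNA, by 6.29 ± 0.21. MAGEE1 had 1 count against 596, a 231-fold ratio (95% counting interval 41.2 to 9120), and its log2 fold change went from -7.62 to -10.5 without Thal-SNS032 replicate 2. CLP1, an RNA processing kinase gene, fell (log2 -5.95 ± 0.35, and -6.67 without Thal-SNS032 replicate 1). HOXB-AS3, which overlaps HOXB5 and HOXB6, fell (-5.72 ± 0.39), as did ZSCAN9 (-5.68 ± 0.38), the ephrin gene EFNB1 (-5.61 ± 0.25) and ZBED6 (-5.53 ± 0.48). In all, 6056 genes were higher and 6538 lower with Thal-SNS032, 4593 and 5014 of them by at least 2-fold. When only library size was used for scaling, 2961 were higher and 10238 lower. Higher genes were then 22.4% of those called against 48.1%, and 1258 of the genes called higher with TMM were called lower.

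LL-K9-3 against SNS032 at the same dose and time gave lower CDK9 and higher CCNT2 and HEXIM1. CDK9 was at 17.7 ± 1.67 against 50.5 ± 2.93 CPM (log2 -1.51 ± 0.12, 95% interval -1.76 to -1.26, adjusted p = 8.00e-11). HEXIM1 was at 117 ± 6.23 against 28.6 ± 1.67 CPM (log2 2.03 ± 0.10, 95% interval 1.82 to 2.24, adjusted p = 5.17e-14). CCNT2 differed by 1.08 ± 0.12 (0.84 to 1.33, adjusted p = 2.30e-08), CCNT1 by -0.49 ± 0.11 (-0.72 to -0.27, adjusted p = 0.000324) and MCL1 by -0.79 ± 0.09 (-0.99 to -0.60, adjusted p = 7.31e-08). AR was not called (log2 0.11 ± 0.11, 95% interval -0.11 to 0.33, adjusted p = 0.366), and its difference was -0.02 without SNS032 replicate 1. KLK3 was not called either (log2 -0.29 ± 0.14, 95% interval -0.59 to 0.01, adjusted p = 0.0768), though it was without SNS032 replicate 3 (log2 -0.41, adjusted p = 0.0211). MYC was lower at log2 -0.22 ± 0.10 (-0.43 to -0.02, adjusted p = 0.0488). That call was lost with DESeq2's size factors (0.0566), with library size (0.085), with the counts of the single files (0.0622) and without SNS032 replicate 1 (0.106), SNS032 replicate 2 (0.0564), LL-K9-3 replicate 1 (0.0961), LL-K9-3 replicate 2 (0.0739) or LL-K9-3 replicate 3 (0.0938).

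Lists lower with LL-K9-3 than with SNS032 were MYC targets, p53 targets, ribosomal proteins, oxidative phosphorylation, luminal markers and zinc finger genes. Of the MYC targets 9 genes rose and 29 fell of 44 (camera adjusted p = 0.000198, and adjusted p = 0.298 with an estimated correlation), with the pseudouridine synthase gene PUS1 at -1.96 ± 0.10. Of the p53 targets 3 genes rose and 18 fell of 30 (adjusted p = 0.0142, and adjusted p = 0.216 with an estimated correlation), with CDKN1A at 98.0 ± 3.86 against 312 ± 26.5 CPM. Of the ribosomal proteins 1 gene rose and 50 fell of 61 (adjusted p = 9.51e-06, and adjusted p = 0.607 with an estimated correlation), with RPSA at -1.05 ± 0.12. Of the oxidative phosphorylation subunits 3 genes rose and 30 fell of 40 (adjusted p = 0.00201, and adjusted p = 0.618 with an estimated correlation), with UQCRFS1 at -2.02 ± 0.10, while RNR2 was higher (log2 0.82 ± 0.11 SE). Of the luminal prostate markers 2 genes rose and 10 fell of 15 (adjusted p = 0.0159, and adjusted p = 0.363 with an estimated correlation), with the prostate transcription factor gene HOXB13 at 42.6 ± 2.33 against 221 ± 13.5 CPM and the luminal keratin gene KRT19 at -1.51 ± 0.11. Of the zinc finger genes 95 genes rose and 247 fell of 479 (adjusted p = 0.0103, and adjusted p = 0.473 with an estimated correlation), with ZNF746 at -1.72 ± 0.10 and, in the other direction, ZNF367 at 2.17 ± 0.11. Adjusted over the list alone, the counts were 9 higher and 30 lower for MYC targets, 1 and 51 for ribosomal proteins, 3 and 31 for oxidative phosphorylation, and the same for the other called lists. Other cell type markers were not called. They were mesenchymal (10 higher and 2 lower of 13, median 1.31, adjusted p = 0.0836), leukocyte and endothelial (3 higher and 0 lower of 4, median 1.89, 0.103), basal (5 higher and 1 lower of 7, median 0.84, 0.148) and neuroendocrine markers (4 higher and 1 lower of 10, median 0.40, 0.286). Close to the threshold lay DNA repair genes (23 higher and 9 lower of 42, or 23 and 10 adjusted over the list alone, adjusted p = 0.0509) and heat shock genes (5 higher and 11 lower of 20, adjusted p = 0.0505). Pro-apoptotic genes, at 0.133, were called without the filter on low counts (0.0251). DNA repair was called with DESeq2's size factors (0.0495), with the counts of the single files (0.0472) and without SNS032 replicate 3 (0.037) or LL-K9-3 replicate 3 (0.0309). Heat shock was called without the filter on low counts (0.00451), with the counts of the single files (0.0377), without the 3 libraries whose files differ (0.0472) and without DMSO replicate 1 (0.047), DMSO replicate 3 (0.047), SNS032 replicate 2 (0.0371), SNS032 replicate 3 (0.0241), LL-K9-3 replicate 1 (0.0337), LL-K9-3 replicate 2 (0.0434), LL-K9-3 replicate 3 (0.0363), Thal-SNS032 replicate 1 (0.0411), Thal-SNS032 replicate 2 (0.0396) or Thal-SNS032 replicate 3 (0.0405).

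Of single genes, LOC728715, COL27A1, PANO1, CCDC150, GRIN3B and LAG3 rose most from SNS032 to LL-K9-3. The collagen gene COL27A1 (chromosome 9, 116917825 to 117074796) was at 74.8 ± 4.07 against 3.29 ± 0.677 CPM (log2 4.50 ± 0.16, adjusted p = 4.23e-16), and LAG3 (chromosome 12, 6881670 to 6887621), an immune checkpoint receptor gene, at 37.5 ± 2.23 against 2.24 ± 0.357 CPM. LOC728715, PANO1, CCDC150 and GRIN3B, each overlapping another gene, rose by 4.66 ± 0.19, 4.43 ± 0.23, 4.27 ± 0.22 and 4.24 ± 0.17. Endothelin 2 (EDN2, chromosome 1, 41944446 to 41950354) was at 2.04 ± 0.393 against 75.2 ± 13.8 CPM (log2 -5.20 ± 0.19, adjusted p = 5.05e-16) and HMOX1 at 2.04 ± 0.784 against 63.6 ± 4.80 CPM (log2 -4.97 ± 0.20). RAB36 fell (log2 -4.12 ± 0.19), and so did GJD3 (-3.33 ± 0.23), the ubiquitin ligase gene RNF41 (-3.23 ± 0.11) and STMN4 (-3.20 ± 0.24). In all, 5606 genes were higher and 5613 lower with LL-K9-3, 3126 and 2572 of them by at least 2-fold.

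LL-K9-3 against Thal-SNS032 gave higher mRNA of P-TEFb, MYC and AR. CCNT1 was at 117 ± 7.02 against 11.7 ± 0.390 CPM (log2 3.33 ± 0.14, 95% interval 3.04 to 3.61, adjusted p = 1.18e-16) and MYC at 201 ± 1.33 against 12.4 ± 2.98 CPM (log2 4.02 ± 0.13, 95% interval 3.75 to 4.28, adjusted p = 1.49e-18). HEXIM1 differed by 2.94 ± 0.12 (2.71 to 3.18, adjusted p = 4.03e-17), CCNT2 by 2.27 ± 0.14 (1.99 to 2.55, adjusted p = 1.27e-13) and AR by 1.82 ± 0.11 (1.59 to 2.06, adjusted p = 2.42e-13). CDK9 differed by 0.57 ± 0.14 (0.28 to 0.86, adjusted p = 0.000680) and MCL1 by 0.36 ± 0.10 (0.16 to 0.56, adjusted p = 0.00161). KLK3 was lower with LL-K9-3, at 6.81 ± 0.401 against 71.5 ± 3.15 CPM (log2 -3.39 ± 0.14, 95% interval -3.67 to -3.11, adjusted p = 6.67e-17).

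Of P-TEFb and its regulators 17 genes rose and 5 fell of 22 with LL-K9-3 (camera adjusted p = 0.0164, and adjusted p = 0.248 with an estimated correlation), while the NELF subunit gene NELFE, which overlaps SKIV2L, was lower at -3.44 ± 0.12. Of the G2 and mitosis genes 30 genes rose and 5 fell of 40 (adjusted p = 0.000115, and adjusted p = 0.234 with an estimated correlation), with CENPF at 4.05 ± 0.13 and, in the other direction, the apoptosis inhibitor gene BIRC5 at -2.49 ± 0.09. Of the zinc finger genes 351 genes rose and 49 fell of 479 (adjusted p = 9.79e-07, and adjusted p = 0.234 with an estimated correlation), with ZNF317 at 4.86 ± 0.18. Lower with LL-K9-3 were ribosomal proteins, where 1 gene rose and 60 fell of 61 (adjusted p = 1.75e-19, and adjusted p = 0.402 with an estimated correlation), with RPS12 at -3.72 ± 0.13. Of the oxidative phosphorylation subunits 0 genes rose and 39 fell of 40 (adjusted p = 4.74e-15, and adjusted p = 0.365 with an estimated correlation), with NDUFS2 at -2.91 ± 0.10 and RNR2 lower beside them (log2 -1.91 ± 0.12 SE). In cholesterol synthesis 2 genes rose and 19 fell of 24 (adjusted p = 0.000447, and adjusted p = 0.234 with an estimated correlation), with LDLR at -2.18 ± 0.09. The cholesterol call was lost with library size as the only scaling (adjusted p = 0.06), and its median went from -0.95 to 0.32, with 13 genes higher and 10 lower. In that scaling 18 P-TEFb regulators were higher and 2 lower, and 431 and 8 zinc finger genes. Counts of the called lists were the same when adjusted over the list alone. MYC targets were not called (adjusted p = 0.0939), but were with library size as the only scaling (0.00255) and without the filter on low counts (0.0229). Without that filter immediate early genes (0.0192) and p53 targets (0.0147) were also called, against 0.0832 and 0.0650 with it.

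NRIP1, CENPJ, FIGN, SH3BP5-AS1, NASP and MAGEE1 were the genes highest with LL-K9-3 relative to Thal-SNS032. The histone chaperone gene NASP (chromosome 1, 46049660 to 46084578) was at 239 ± 8.84 against 5.77 ± 1.78 CPM (log2 5.37 ± 0.14, adjusted p = 2.00e-19) and NRIP1 (chromosome 21, 16333556 to 16437126), a nuclear receptor corepressor gene, at 113 ± 20 against 1.44 ± 0.210 CPM. The centriole gene CENPJ rose by 5.90 ± 0.26, FIGN by 5.62 ± 0.29, and SH3BP5-AS1, antisense to SH3BP5, by 5.53 ± 0.29, or 6.37 without Thal-SNS032 replicate 3. MAGEE1 had 317 counts against 1, a 168-fold ratio (95% counting interval 29.9 to 6650), and its log2 fold change went from 7.16 to 10.0 without Thal-SNS032 replicate 2. HCG15 was lower (log2 -7.67 ± 0.15), as were KLKP1 (-7.07 ± 0.14), EML2-AS1 (-5.77 ± 0.15), the lipoxygenase gene ALOX15 (-5.71 ± 0.18), the complex I assembly gene NDUFAF3 (-5.28 ± 0.15) and MIR7641-2 (-5.89 ± 0.31), which was at -6.52 without LL-K9-3 replicate 1. In all, 6847 genes were higher and 5774 lower, 5265 and 4206 of them by at least 2-fold. Library size as the only scaling gave 10863 higher and 2629 lower. Higher genes then made up 80.5% of those called against 54.3%, and 1419 of the genes called lower with TMM were called higher.

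Calls against DMSO were shared between compounds more often than independent lists would give. SNS032 and LL-K9-3 shared 2787 higher and 3093 lower genes, against 1794 and 2052 for independent lists of these sizes, and 2074 genes were called in opposite directions against 3839. SNS032 and Thal-SNS032 shared 2492 higher and 3034 lower genes (1831 and 2451), with 3324 opposite (4244). LL-K9-3 and Thal-SNS032 shared 2727 higher and 3649 lower genes (2040 and 2616), with 3105 opposite (4635). These counts are with TMM. With library size as the only scaling the shared higher and lower genes were 1471 and 5139 for SNS032 and LL-K9-3 (767 and 3910 for independent lists). They were 770 and 6641 for SNS032 and Thal-SNS032 (419 and 5938) and 822 and 6564 for LL-K9-3 and Thal-SNS032 (519 and 5732). These comparisons use the same DMSO libraries. With TMM, 20 simulations of unchanged groups and controls gave a mean of at most 0.1 shared calls per direction, which leaves out real effects. Across the 15763 genes, which are not independent replicates, the Pearson correlation of log2 fold changes was 0.510 for SNS032 and LL-K9-3 (Spearman 0.437, simulated mean 0.447). It was 0.309 for SNS032 and Thal-SNS032 (0.268, simulated 0.355) and 0.379 for LL-K9-3 and Thal-SNS032 (0.348, simulated 0.366). The covariances of 0.745, 0.654 and 1.04 stood against simulated means of 0.022, 0.026 and 0.022, differences of 0.723, 0.628 and 1.02. With 3 controls no split keeps at least 2 libraries in each part, and part of the excess in shared calls can come from the shared controls.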

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

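The counts of the single files and the fits without DMSO replicate 1, DMSO replicate 2 and Thal-SNS032 replicate 3 together were chosen after seeing the data. Over all alternatives run, values of named genes kept direction and side of the threshold in 5282 cases, lost the call in 31, gained it in 4 and changed direction in 3. Most named genes were picked for large or clear changes in these same data, so this stability was largely fixed beforehand and does not describe all genes. Of the 5282 cases, 3173 left out 1 library, in part from groups outside the comparison. Single lists kept their call or its absence in 2867 cases, lost it in 59, of which 51 came from the estimated correlation, and gained it in 38. Counts of genes stayed within 1.5 times in 233 cases and moved further in 7. Those 7 came from library size as the only scaling. It gave 3124 genes higher with SNS032 (5039 with TMM), 2113 higher and 11714 lower with Thal-SNS032 (5728 and 7019), 2961 and 10238 for Thal-SNS032 against SNS032 (6056 and 6538), and 10863 and 2629 for LL-K9-3 against Thal-SNS032 (6847 and 5774). This follows from the TMM factors, which set the level of no change. Which scaling lies nearer the amount of mRNA per cell was not tested. With an estimated correlation between genes, the lists called went from 12, 10, 8, 6, 9 and 6 in the order of the comparisons to 0 in each by camera, with 8, 4, 5, 1, 7 and 5 lists at an unadjusted p under 0.05; fry, which tests against no change, called 23, 23, 24, 22, 24 and 22. The fold change of AR changed direction with library size as the only scaling, to -0.20 with SNS032 (0.15) and -0.07 with LL-K9-3 (0.26), and for LL-K9-3 against SNS032 it ran from -0.02 to 0.19 over the fits that left out a library (0.11), at -0.02 without SNS032 replicate 1. None of the 3 was called in the changed direction. Calls lost in other alternatives included CCNT2 with Thal-SNS032 (adjusted p = 0.0576) and the heat shock list with LL-K9-3 (adjusted p = 0.146), both without the 3 libraries whose files differ. That fit has 1 DMSO and 2 Thal-SNS032 libraries, and the lone DMSO library was assumed to vary like the other groups. The fold change of CCNT2 was larger in it, at -0.39 (-0.31). The same fit gained cholesterol synthesis with SNS032 (adjusted p = 0.0442 against 0.163) and p53 targets with Thal-SNS032 (0.0435 against 0.067). Whether the libraries left out or the smaller groups changed these calls was not tested. Leaving out 1 library at a time, genes higher ran from 4824 to 5098 with SNS032, 5383 to 5852 with LL-K9-3 and 5538 to 5815 with Thal-SNS032.

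The replicate numbers were checked for pairing. Deviations of libraries with the same number had correlations between -0.298 and 0.106, and in 0 of the 6 comparisons did all pairs exceed 0.1, so the numbers were not taken to pair the samples. With the replicate number as a block, 4849 genes were higher and 5316 lower with SNS032, 5439 and 5704 with LL-K9-3, and 5643 and 6941 with Thal-SNS032, each within 1.5 times of the counts without it. The block ended the calls of CCNT2 with Thal-SNS032 (log2 -0.31, adjusted p = 0.0571) and of MYC for LL-K9-3 against SNS032 (log2 -0.22, adjusted p = 0.0722). It brought the heat shock list for LL-K9-3 against SNS032 under the threshold (adjusted p = 0.0444), and it changed no other call of a named gene or list. Depth limits genes with few counts, where the fold depends on single reads. A planned scaling on mitochondrial mRNAs was not run because the table holds none.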

Other observations

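The genes of the next 2 paragraphs, the grouping of genes by span and the test of genomic DNA for LL-K9-3 were chosen after the result was seen, and the grouping by 3′ neighbours was first made for Thal-SNS032 and taken up for LL-K9-3 from the same table. Single kallikrein genes of chromosome 19, which encode secreted serine proteases, are given here. They were not tested as a group and did not all move alike. With Thal-SNS032, KLKP1 rose from 5.95 to 724 CPM, KLK4 (51409608 to 51413994) from 170 to 483 CPM (log2 1.5 ± 0.10 SE, adjusted p = 1.27e-12), KLK1 from 24.8 to 52.5 CPM (1.08 ± 0.11) and KLK11 from 3.34 to 10.8 CPM (1.69 ± 0.20). KLK2 rose by 0.49 ± 0.10 (adjusted p = 0.000173), and KLK15 was at 2.46 against 3.28 CPM (adjusted p = 0.132). With library size as the only scaling KLK1, KLK2 and KLK4 turned to -0.52, -1.11 and -0.09, while KLK11 stood at 0.09, KLK3 at 0.61 and KLKP1 at 5.32. With SNS032 and LL-K9-3, KLK1 was at 7.72 and 6.46 CPM and KLK2 at 16.4 and 11.5 against 39.8 CPM. KLK14 was at 8.50 CPM with LL-K9-3 and 0.369 with DMSO.

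The 2673 genes that span at least 100000 bp had median log2 fold changes of -0.42 with SNS032, 0.19 with LL-K9-3 and -0.47 with Thal-SNS032, against 0.02, -0.16 and -0.12 for the 4191 genes under 10000 bp. The Spearman correlation with span, over 15763 genes that are not independent, was -0.159, 0.094 and -0.046, and 0.224 for LL-K9-3 against SNS032. Other gene properties gave larger values in some comparisons. The correlation with exon length was -0.195, 0.040 and -0.266 and that with GC content 0.277, 0.010 and 0.138 in the same order. For LL-K9-3 against SNS032 they were 0.201 and -0.218.

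Ribosomal protein and oxidative phosphorylation mRNAs were higher and zinc finger mRNAs lower with Thal-SNS032. Among 10000 random lists matched on exon length the ribosomal protein median of 2.62 lay 1.13 above the upper limit of the central 95% of their medians. The margin was 2.26 among lists matched on GC content and 1.97 among lists matched on genomic span. In each matching the oxidative phosphorylation list lay above and the zinc finger list below nearly all random lists (percentiles 100 and 0). Medians of the random lists centred on 0.78 for exon length, -0.27 for GC content and -0.18 for span, below the 2.62 of the ribosomal proteins. Random lists hold genes drawn singly, while list members vary together (estimated correlation 0.917 for ribosomal proteins and 0.658 for oxidative phosphorylation). The central 95% is therefore too narrow, by an amount that was not computed, and the percentiles are not p-values. The matching thus does not exclude these biases. Each matching took 1 property, and abundance was not matched. An effect of the compound on synthesis or on the stability of these mRNAs stays open and was not tested.

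MIR663A, MIR663AHG and MIR7641-2 rose with Thal-SNS032. If reads of ribosomal RNA were counted there, genes of ribosomal DNA would rise too, but they had 0 counts over the 12 libraries, so that test decides nothing and the explanation stays open. The summed CPM of 399 olfactory receptor genes, taken as a proxy for reads of genomic DNA, had a log2 ratio of -0.08 with Thal-SNS032 (from -0.74 to 0.41 between single libraries). This argues against genomic DNA only at the scale of these rises. The sum held 37 to 222 counts per library, on 13 to 42 of the receptor genes, and it fell with SNS032 (log2 -1.10). Whether it holds transcripts of receptor genes was not tested. A change in transcription of MIR663A, MIR663AHG and MIR7641-2 by the compound was not tested either.

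Genes low with DMSO (under 1 CPM) that lie within 10000 bp past the 3′ end of a gene at 10 CPM or more were higher with LL-K9-3. The median log2 fold change of these 811 genes was 1.66, against 0.33 for 491 genes as near before a 5′ end but not past a 3′ end. The difference was 1.33 (bootstrap interval 1.14 to 1.58, permutation p = 1e-04, the smallest that 10000 permutations allow). Genes near both kinds of end were counted among the 811, so the sets are not mirror images. Intervals here and the p resample genes, which are not independent, and do not measure the spread between cultures. In single libraries, each set against the mean of the DMSO libraries, the difference was 1.36 to 1.44 with LL-K9-3. Single DMSO libraries gave -0.06 to 0.02, but they make up that mean, so values near 0 were largely fixed beforehand. On group means the difference was 0.54 with SNS032 (bootstrap interval 0.36 to 0.71) and 0.30 with Thal-SNS032 (0.08 to 0.52), so the pattern was not particular to LL-K9-3. Single SNS032 libraries gave 0.367 to 0.573, and the SNS032 intervals by distance from the neighbour each lay above 0. Single Thal-SNS032 libraries gave 0.015 to 0.242, and the Thal-SNS032 intervals by distance each included 0. The summed CPM of olfactory receptor genes had a log2 ratio of at most 0.95 between single libraries. That sum rests on few counts, and transcripts in it could hide a change of this size, so reads of genomic DNA stay open. A longer last exon of the neighbour is argued against by a difference of 1.23 (0.83 to 1.56) at over 5000 and up to 10000 bp. Transcription past the 3′ end of the neighbour stays open: the gain had a Spearman correlation of 0.25 (0.18 to 0.32) with the level of the upstream gene, between the 0.1 and 0.3 set beforehand, and of -0.01 for genes before a 5′ end. Other effects of the compound were not tested.

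For each comparison the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and 1 split, the real one, called the most genes. The real splits called 10544 genes with SNS032, 11489 with LL-K9-3 and 12747 with Thal-SNS032 against DMSO, 11219 for LL-K9-3 against SNS032, 12594 for Thal-SNS032 against SNS032 and 12621 for LL-K9-3 against Thal-SNS032. The highest of the other splits called 0 by edgeR in each, with 721, 417, 159, 390, 344 and 202 genes at an unadjusted p under 0.05. Each other split mixes libraries of both treatments, which widens the spread within its groups where so many genes differ. Its lack of calls was thus largely fixed beforehand, and no conclusion is drawn from it.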
